A study of Drosophila melanogaster with 46 samples.

How the data were processed

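The series holds 46 hybridisations of 2-colour spotted arrays of Drosophila melanogaster genes, each with a different RNA in each channel except for 2 arrays that carried RNA of mixed sexes in both. Per the labels, adult flies of 3 to 5 days kept at 25 C gave whole-fly RNA or RNA of dissected gonads and of the carcasses left after dissection. Poly(A) mRNA was selected, 200 ng were made into a Cy3 or Cy5 probe, each pair of probes was hybridised between 2 subarray slides, and the slides were scanned on a GenePix 4000A, also per the labels. The deposited values are log ratios of the 2 channels for 31464 spots per array. They have both signs, reach 6.18 in absolute size, and run in opposite directions on dye-swapped arrays. The authors' background correction, normalization and filter behind missing values are not given in the sources used here, nor is the log base. The deposited log ratios were taken as log2. A base of 10 would need ratios beyond what the scanner can record, but a natural log is not excluded, in which case every log2 value here would be larger by a constant factor while tests and counts without a fold threshold would stay. Array medians as deposited lay between -0.034 and 0.066, so the values had been centred near 0 by an unnamed method. Neither the file nor the labels say which channel is the numerator. A control fixed beforehand settled the direction as likely. With channel 1 over channel 2, the yolk protein genes Yp1, Yp2 and Yp3 were higher in whole females, and the testis genes betaTub85D, Mst87F and dj were higher in testis than in ovary, on 4 of 4 arrays each.

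The comparisons, the tests, the 18 gene lists, the rule for the genes named in the text and all alternatives not described as added later were fixed before the data were examined. Each of 15 comparisons used arrays carrying the same pair of RNAs, 7 of them with 4 arrays and 8 with 2. Arrays numbered alike, such as 1a and 1b, share a dye orientation. The labels do not say whether such repeats came from separate extracts. The p-values therefore measure the spread between arrays, pooled over comparisons, part of which may be technical. The number of arrays limits the precision. In the tudor comparisons numbered 17 to 21 all arrays had 1 dye orientation.

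Duplicate spots were averaged, which gave 15732 elements, 7956 of them on the first subarray and 7776 on the second. An array measured between 7994 and 14881 elements (median 12375). All 46 arrays measured 4342 elements, and 95 were measured on none. The correlation across elements between duplicate spots lay between 0.798 and 0.987 on the arrays of the comparisons (median 0.965) and between 0.602 and 0.701 on the mixed RNA arrays. The platform table gave 1 gene for 12586 elements, several for 73 and none for 3073, and elements with several genes were left unnamed. Of the elements with 1 gene, 12106 matched the RefSeq gene table of the Release 6 assembly, which changed 0 symbols and was used otherwise only to place genes on the X or on chromosomes 2, 3 and 4. The arrays covered 10850 genes, 1337 of them with more than 1 element and 1666 on the X. For a gene with several elements, the element measured on most arrays stood for it, with the lowest identifier deciding ties. Entries of the lists that the platform table does not name were not analysed here.

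Each array was centred on its median. All arrays were fitted together with limma, with 1 coefficient per comparison, signed by dye orientation, and a dye coefficient per element shared by all arrays. The hybridisation number was a random block. Its estimated correlation, -0.0875, gave more calls than independent arrays. Variances were moderated with 4.31 prior degrees of freedom. The fit used generalised least squares over the arrays that measured each element, and its statistics differed from limma's own by at most 2.8e-14. The median residual SD was 0.193. An element was tested where at least 2 arrays of a comparison measured it. It was called at a Benjamini-Hochberg adjusted p below 0.05 within that comparison. The dye coefficient passed that threshold for 3799 of 14849 elements, with a median size of 0.0632 over all of them. Log2 values are given ± SE, and every adjusted p of an element is limma's. Both rest on 1 moderated residual variance per element over all comparisons, not on the spread of a comparison's own arrays. The n beside an SE is the number of arrays of that comparison.

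The fit departs from the plan in a single respect, chosen after seeing the data. On arrays 7b and 8b of the comparison of ovary with female carcass, the values of the first subarray ran opposite to 7a, 8a and to the second subarray of the same arrays. These 9626 values were left out, and the comparison was also run with them as deposited, with them turned, and without both arrays. The other alternative added later fitted the difference between carcass and tudor sex effects on its own arrays only.

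Text names genes by a fixed rule. In the comparisons of 4 arrays, in testis against male carcass and in tudor females against tudor males, these are the 10 highest and 10 lowest log2 ratios among genes called with a value and the same sign on every array and with a symbol other than an annotation number. In the remaining comparisons they are the 3 highest and 3 lowest. Some are left out of the text, and members of the fixed lists are named beside them. The lists cover yolk proteins, eggshell, oogenesis, spermatogenesis, male accessory gland, dosage compensation, sex determination, somatic sex-biased genes of head and fat body, muscle, photoreceptor, neuronal genes, digestive enzymes, antimicrobial and immune genes, odorant binding proteins, ribosomal proteins, mitochondrial energy genes, DNA replication and cell cycle, and widely expressed controls. They were written from general knowledge of the fly, not chosen on these samples. Each list was set against all other genes with limma's cameraPR at a preset correlation of 0.01 and again with the correlation estimated, with Benjamini-Hochberg adjustment over all lists and comparisons. The shares of X-linked and autosomal genes called were compared by two-sided Fisher's exact test, adjusted over 34 tests.

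Other settings were arrays taken as independent, repeats averaged first, no dye coefficient, each comparison on its own arrays, and a coefficient per RNA source. Further ones were arrays scaled to the same median absolute deviation, no centring, elements measured on all arrays, a 2-fold threshold, and each array left out in turn. The procedure was tested on simulated arrays with the real spreads and missing values. Per comparison, 67, 67 and 66 elements changed by log2 0.5, 1 and 2, with block correlations estimated at 0.167 to 0.173, not -0.0875. For females against males 49.3, 94.0 and 98.5% were recovered, with 3.59% of calls false. For testis against male carcass this was 46.3, 79.1 and 100%, with 1.96% false, and for tudor flies by sex 46.3, 94.0 and 100%, with 6.43% false. These shares may not hold for the real arrays. Work was done in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.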

Results

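Transcript levels of adult flies were compared on 46 2-colour arrays. The RNAs came from whole females and males, dissected ovaries and testes, the carcasses left after the gonads were removed, XX flies mutant for doublesex, and XX and XY flies mutant for transformer 2. They also came from the progeny of tudor mutant mothers, which lack a germline. The genes transformer 2 and doublesex act in the pathway that sets somatic sex, and XX flies without transformer 2 function develop a male soma. By the title of the series the subject was sex-biased expression. Gonads, carcasses and germline-less flies set germline and gonad against the rest of the body, and the mutants somatic against chromosomal sex. Per the labels the flies that were not mutant for these genes came from a yellow white strain, whose name differs between label fields on some arrays, and the mutants from stocks with other markers. Genetic background therefore differs along with the mutation wherever mutants were set against that strain, and the arrays cannot tell these apart. There were 4 arrays each for 7 comparisons and 2 arrays each for 8. Arrays of a comparison with swapped dyes correlated across elements at a median r of 0.715 (27 pairs, from 0.0637 to 0.934), and repeats in the same orientation at 0.874 (17 pairs, from 0.536 to 0.949). These pairs leave out ovary against female carcass. As deposited, 4 of its 6 pairs were below 0, with -0.139 for 7a and 7b, -0.0075 for 8a and 8b, -0.170 for 7a and 8b and -0.109 for 7b and 8a, against 0.857 for 7a and 8a and 0.870 for 7b and 8b. Elements are not independent replicates. A log2 ratio of 1 is a 2-fold difference if the deposited values are log2, as taken here, and the direction of every ratio is likely rather than stated.

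Whole females had more transcript of DNA replication and cell cycle genes and of each of 3 yolk genes than whole males, and males more of sperm and accessory gland genes. The yolk and eggshell lists lost their calls with an estimated correlation. Yp2, a yolk protein gene, was 4.02 ± 0.29 (SE, n = 4 arrays) higher on the log2 scale in females. Its SD over these 4 arrays was 1.07, as the SE draws on the spread over all comparisons. The gene dhd, for a thioredoxin needed in the egg, was 3.36 ± 0.28 higher, gnu, a regulator of the first embryonic divisions, 3.08 ± 0.19, and CycB, the mitotic cyclin B, 2.56 ± 0.15 (n = 4 arrays). Among the lowest log2 ratios of females over males were those of S-Lap7, a sperm aminopeptidase, at -3.48 ± 0.17, the serpin gene Spn77Bb at -3.19 ± 0.16, and EbpII, an ejaculatory bulb protein, at -3.06 ± 0.18. Mst57Dc, an accessory gland transcript, was at -3.05 ± 0.13 and Mst87F, a sperm tail protein, at -2.94 ± 0.16 (limma, adjusted p = 1.19e-12 for Yp2, adjusted p = 1.95e-15 for S-Lap7, adjusted p = 3.48e-18 for Mst57Dc). Among the other female-biased genes were Yp1 (3.51 ± 0.27), Yp3 (2.83 ± 0.27), the vitelline membrane gene Vm32E (2.57 ± 0.20), me31B, a repressor of maternal mRNA translation (2.45 ± 0.16), and RnrL, a ribonucleotide reductase subunit (2.34 ± 0.16). Among the other male-biased genes, S-Lap8 was at -3.22 ± 0.24, and the sperm chromatin protein gene Mst77F at -2.99 ± 0.14.

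By list, 3 of 3 yolk genes were higher in females (3 adjusted over the list alone, median 3.51, adjusted p = 0.00014). The yolk list had adjusted p = 0.0677 with an estimated correlation. Of 11 eggshell genes 10 were higher in females (10 adjusted over the list alone, adjusted p = 3.69e-05). For eggshell genes this was adjusted p = 0.134 with an estimated correlation. Of 45 oogenesis genes 37 were higher and 4 lower in females (the same counts adjusted over the list alone, adjusted p = 3.4e-09), with osk, the posterior determinant, at 1.97, vas, a germline RNA helicase, at 1.85, and piwi at 1.403. Oogenesis genes had adjusted p = 0.0872 with an estimated correlation. DNA replication and cell cycle genes were higher in females in 20 of 25 cases and lower in 1 (21 and 1 adjusted over the list alone, adjusted p = 5.06e-11). All 18 accessory gland genes were lower in females (18 adjusted over the list alone, median -1.90, adjusted p = 3.83e-19), sex peptide, SP, at -2.68 among them. Of 32 spermatogenesis genes 29 were lower in females (29 adjusted over the list alone, median -1.50, adjusted p = 1.36e-18), with betaTub85D, the testis tubulin, at -2.84 and dj, a sperm tail gene, at -2.86. The single member higher in females was twe, a phosphatase that acts in meiosis, at 0.53, a call lost without array 1a (0.40), 1b (0.48) or 2b (0.44). Ribosomal protein genes were higher in females in 32 of 38 cases and lower in 3 (the same adjusted over the list alone, median 0.90, adjusted p = 0.000337). Digestive enzyme genes were higher in 16 of 26 and lower in 3 (16 and 3 adjusted over the list alone, adjusted p = 0.022). The ribosomal protein and digestive enzyme lists had adjusted p = 0.566 and adjusted p = 0.745 with an estimated correlation.

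Photoreceptor genes were lower in females in 10 of 12 cases and higher in 1 (the same adjusted over the list alone, adjusted p = 0.0406), Arr1, a visual arrestin, at -1.09. For photoreceptor genes this was adjusted p = 0.462 with an estimated correlation. That list lost its call when arrays were scaled to the same spread (adjusted p = 0.0788). Odorant binding protein genes were lower in 10 of 23 (10 adjusted over the list alone, adjusted p = 0.00452). That list had adjusted p = 0.301 with an estimated correlation. Not shifted as lists were muscle genes (15, 11 of them lower in females, adjusted p = 0.052) and neuronal genes (17, 10 lower, adjusted p = 0.108). Nor were dosage compensation (6, adjusted p = 0.38), sex determination (7, adjusted p = 0.526), somatic sex-biased genes (6, adjusted p = 0.879), immune genes (11, adjusted p = 0.879), mitochondrial energy genes (17, adjusted p = 0.898) and widely expressed controls (3, adjusted p = 0.172). In the dosage compensation list msl-2, the male-specific subunit of the complex, was at -0.43 and called higher in males.

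In all, limma called 3755 of 12987 elements higher in females and 3610 higher in males, of which 415 and 918 differed at least 2-fold. X-linked genes were called higher in females more often than autosomal genes (35.4 against 29.9%, odds ratio 1.28, 95% confidence interval 1.14 to 1.45, Fisher's exact test, adjusted p = 0.00013) and higher in males less often (24.04 against 32.2%, odds ratio 0.666, Fisher's exact test, adjusted p = 3.27e-09). The female excess was lost with a 2-fold threshold (odds ratio 1.01) and on elements measured by all arrays (1.26), as was the male deficit on the latter (0.782). Scaling the arrays to the same spread left 4383 calls and brought Yp2 to 2.64 and S-Lap7 to -2.25.

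**Figure D1:**
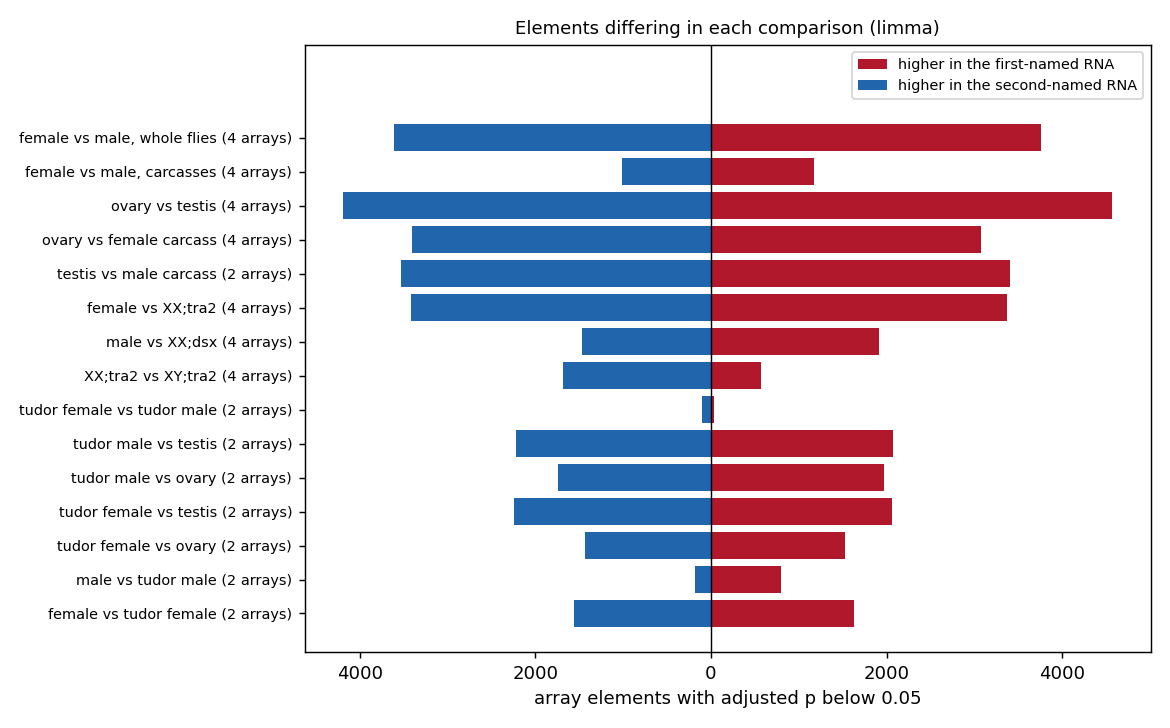
Number of array elements (horizontal axis, from 0 to both sides) called by limma at an adjusted p below 0.05 in each comparison, in red for those higher in the first-named RNA and in blue for those higher in the second. Ovary against testis had most calls (4569 and 4189) and tudor females against tudor males fewest (39 and 104).

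Without gonads, females still exceeded males in yolk and digestive enzyme genes, and males exceeded females in genes of the accessory gland and ejaculatory duct. In carcasses Yp2 was 4.99 ± 0.29 higher in females (SE, n = 4 arrays), Yp1 4.21 ± 0.27 and Yp3 4.07 ± 0.27. Fad2, the desaturase that makes female pheromone dienes, was 2.90 ± 0.15 higher, Send1, a protease of the sperm storage organs, 2.46 ± 0.22, and the gut protease genes Jon66Cii and Jon25Biii 2.19 ± 0.21 and 2.18 ± 0.24 (n = 4 arrays). Among the lowest in females over males were Spn77Bb at -2.26 ± 0.16, and EbpII at -2.20 ± 0.18. Obp56g, an odorant binding protein gene also used in the ejaculatory bulb, was at -1.89 ± 0.10, and Acp36DE, a seminal protein that acts in sperm storage, at -1.85 ± 0.19 (limma, adjusted p = 2.66e-13 for Yp2, adjusted p = 5.3e-16 for Fad2, adjusted p = 2.55e-15 for Obp56g).

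The 3 yolk genes were all higher in female carcasses (3 adjusted over the list alone, median 4.21, adjusted p = 9.17e-27). Of 26 digestive enzyme genes 23 were higher in females (23 adjusted over the list alone, median 1.597, adjusted p = 1.21e-38), Jon66Ci at 1.79 among them. Accessory gland genes were lower in 17 of 18 cases (17 adjusted over the list alone, median -1.09, adjusted p = 1.62e-34). In the somatic list of head and fat body 3 of 6 genes were higher in females and 2 lower (3 and 3 adjusted over the list alone, adjusted p = 2.58e-05). The female fat body gene fit was at 1.90, Obp99a at 1.65, and Cyp4d21, a P450 gene of the male head fat body, at -1.27. These 4 lists kept their calls with an estimated correlation. Ribosomal protein genes were higher in female carcasses in 25 of 34 cases (29 adjusted over the list alone, adjusted p = 4.67e-09), and immune genes in 6 of 11, with 1 lower (the same adjusted over the list alone, adjusted p = 0.0231). The ribosomal protein and immune lists had adjusted p = 0.274 and adjusted p = 0.151 with an estimated correlation. Neuronal genes were lower in 6 of 17 (7 adjusted over the list alone, adjusted p = 0.000379). For neuronal genes this was adjusted p = 0.207 with an estimated correlation.

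Genes of the removed organs were called here too. Eggshell genes were higher in female carcasses in 6 of 10 cases (8 adjusted over the list alone, adjusted p = 3.69e-05), with Vm32E at 1.31, and oogenesis genes in 14 of 37 (14 higher and 1 lower adjusted over the list alone, adjusted p = 0.000956). Eggshell and oogenesis genes had adjusted p = 0.117 and adjusted p = 0.389 with an estimated correlation. DNA replication and cell cycle genes were higher in 7 of 18 (7 adjusted over the list alone, adjusted p = 0.0231), CycB at 1.11. The DNA replication list had adjusted p = 0.483 with an estimated correlation. Spermatogenesis genes were lower in 12 of 23 cases (15 adjusted over the list alone, adjusted p = 7.93e-09), with Mst87F at -1.08. For spermatogenesis genes this was adjusted p = 0.134 with an estimated correlation. Over the whole array limma called 1169 of 11690 elements higher in female and 1016 in male carcasses, 123 and 108 of them at least 2-fold. Without array 4a 797 calls were left, on the 4 arrays alone 174, without a dye coefficient 1086, and Mst87F was no longer called on the 4 arrays alone. On the X, fewer genes were called higher in male carcasses than on the autosomes (6.32 against 9.34%, odds ratio 0.654, Fisher's exact test, adjusted p = 0.000667). The shares called higher in female carcasses did not differ detectably (10.0 against 10.5%, odds ratio 0.951, Fisher's exact test, adjusted p = 0.679). Restricted to elements measured by all arrays the male odds ratio was 0.753 and past no threshold, and the female one 0.637 and past it.

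The sex effect was tested directly for a difference between whole flies and carcasses, and 4297 of 11364 elements differed (limma). The female over male ratio was higher in whole flies for 2050 and higher in carcasses for 2247. At least 2-fold differences numbered 110 and 578. A higher ratio in carcasses may be a stronger female bias or a weaker male bias there. Overlaps here and elsewhere were counted among elements tested in both comparisons. Of 1140 such elements higher in female carcasses, 585 (51.3%) were also higher in whole females where 326.8 would be shared by independent lists, and of 975 higher in male carcasses 637 (65.3%) were also higher in whole males where 268.4 would. Log2 ratios of the carcass and whole-fly comparisons correlated across elements at 0.606. No array was shared, but RNA may have been, and part of each overlap may come from that. With arrays scaled to the same spread 33.0% of 1000 differences, rather than 47.7% of 4297, were toward females in whole flies, and 976 elements were called the same way under both settings.

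Ovary and testis had the most calls of the 15 comparisons, with spermatogenesis and accessory gland genes higher in testis RNA. The lists higher in ovary lost their calls with an estimated correlation. In ovaries over testes dhd was 3.37 ± 0.28 higher (SE, n = 4 arrays), the chorion gene Cp38 3.32 ± 0.31, gnu 3.08 ± 0.19, Vm32E 2.89 ± 0.20, and dec, another eggshell gene, 2.70 ± 0.19. The posterior determinant osk was 2.48 ± 0.20 higher and yl, the yolk receptor, 2.40 ± 0.17. Toward testis, w-cup, a transcript of late spermatids, was at -4.61 ± 0.21, and the sperm tail gene Mst98Cb at -4.23 ± 0.17. S-Lap7 was at -4.09 ± 0.17, Mst77F at -4.07 ± 0.14 and Gpdh3, a glycerol-3-phosphate dehydrogenase gene, at -4.05 ± 0.19. Each was called by limma (n = 4 arrays, adjusted p = 3.95e-12 for dhd, adjusted p = 6.46e-12 for osk, adjusted p = 1.43e-15 for w-cup, adjusted p = 9.36e-22 for Mst77F).

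All 12 eggshell genes were higher in ovary (12 adjusted over the list alone, median 1.48, adjusted p = 1.66e-07), as were 35 of 45 oogenesis genes, with 3 lower (36 and 5 adjusted over the list alone, adjusted p = 1.83e-06). Eggshell and oogenesis genes had adjusted p = 0.0632 and adjusted p = 0.19 with an estimated correlation. The anterior determinant bcd was at only 0.21, a call lost without array 5a (0.15) or 6a (0.19). Spermatogenesis genes were lower in ovary in 31 of 34 cases (31 adjusted over the list alone, median -2.37, adjusted p = 3.83e-19), with betaTub85D at -3.34, Mst87F at -3.77 and dj at -3.86. The meiotic gene twe was not called (0.022). All 18 accessory gland genes were lower in ovary than in testis (18 adjusted over the list alone, median -2.35, adjusted p = 2.51e-13), SP at -3.02. DNA replication and cell cycle genes were higher in ovary in 20 of 25 and lower in 1 (the same adjusted over the list alone, adjusted p = 3.69e-05). The DNA replication list had adjusted p = 0.211 with an estimated correlation. The 3 yolk genes were each called higher in ovary (3 adjusted over the list alone), Yp1 at 1.88 and Yp2 at 2.14, but the list did not stand apart from all genes (adjusted p = 0.15). Odorant binding protein genes were lower in ovary in 12 of 19 and higher in 2 (the same adjusted over the list alone, adjusted p = 0.0287), a list call lost with arrays scaled to the same spread (adjusted p = 0.0544). For odorant binding protein genes this was adjusted p = 0.426 with an estimated correlation.

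Over all elements limma called 4569 of 13128 higher in ovary and 4189 higher in testis, 816 and 1713 at least 2-fold. Ovary bias was called for X-linked genes more often than for autosomal genes (42.5 against 33.4%, odds ratio 1.47, Fisher's exact test, adjusted p = 8e-10). Testis bias was called less often (28.2 against 37.7%, odds ratio 0.647, Fisher's exact test, adjusted p = 4.36e-11), the latter lost on elements measured by all arrays (0.791). Of 3728 elements higher in whole females, 3049 (81.8%) were higher in ovary and 84 in testis, where independent lists would share 1327 with ovary. Of 3354 higher in whole males, 2578 (76.9%) were higher in testis where 1043 would be. Log2 ratios of the whole-fly and gonad comparisons correlated across elements at 0.899, and part of the overlap may come from shared RNA. With arrays scaled to the same spread 5090 calls were left and sizes fell, w-cup to -2.45 and dhd to 1.81.

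**Figure D2:**
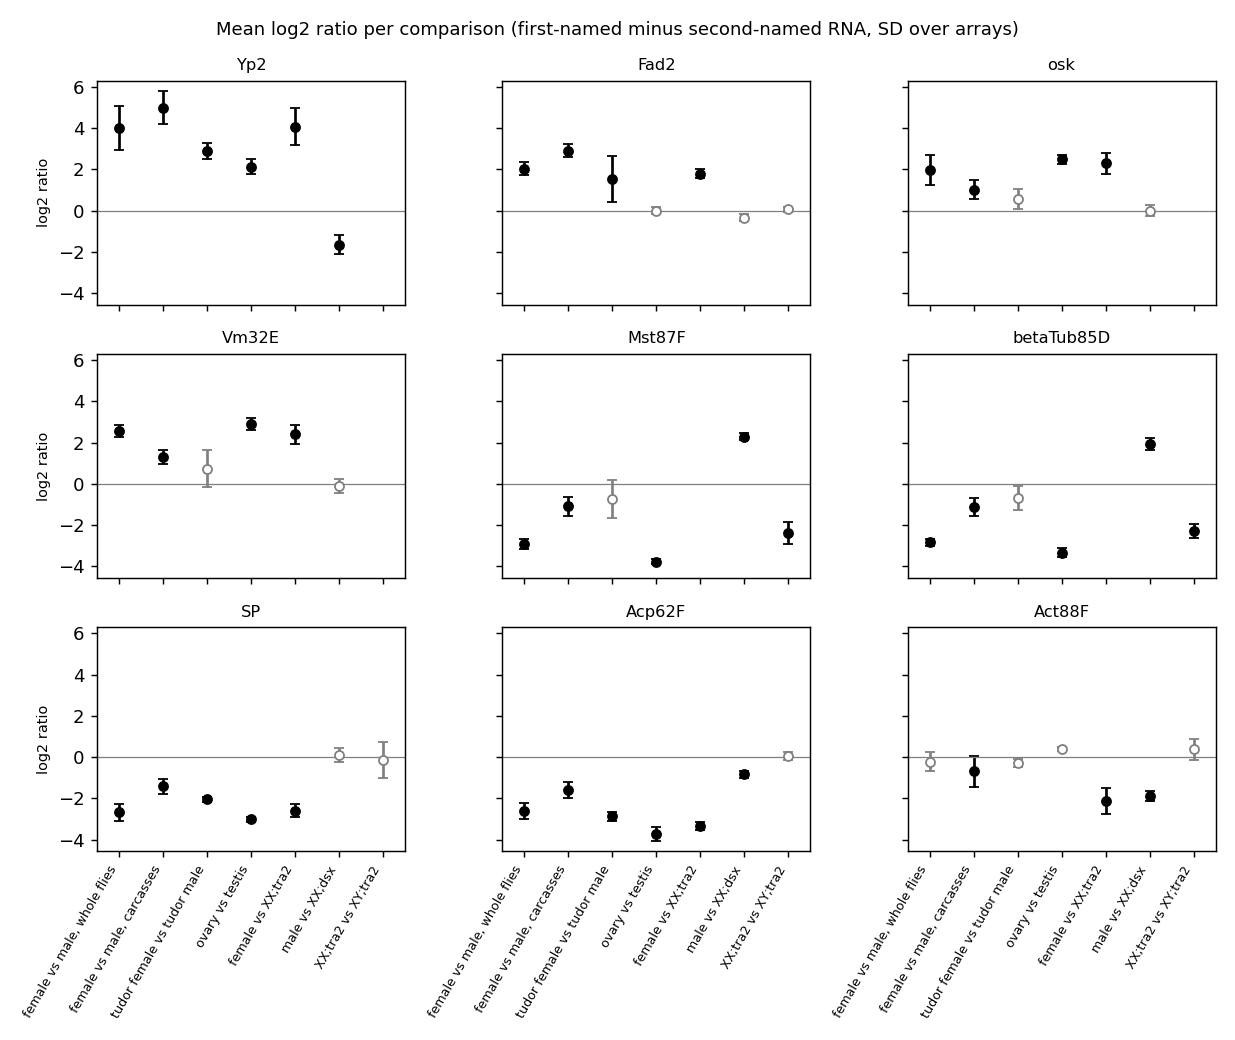
Log2 ratio (vertical axis, first-named minus second-named RNA) of 9 genes in 7 comparisons, as the mean over arrays with bars for the SD, black for genes called by limma and open grey for those not called, and no symbol where a gene was not tested. The mean of Yp2 was 4.02 in whole flies, 4.99 in carcasses and 2.89 in tudor flies, and that of Mst87F was -2.94 in whole flies and -1.08 in carcasses.

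The female carcass exceeded ovaries in muscle and somatic sex-biased genes. The lists higher in ovary, and digestive enzyme genes, higher in the carcass, lost their calls with an estimated correlation. In ovary, Vm32E was 2.10 ± 0.20 higher (SE, n = 4 arrays), gnu 2.00 ± 0.19, yl 1.99 ± 0.17, CycB 1.84 ± 0.15, vas 1.71 ± 0.18, RnrL 1.66 ± 0.16 and Nop60B, a pseudouridine synthase gene, 1.59 ± 0.11. In the carcass direction Cyp4g1, the oenocyte P450 of cuticular hydrocarbon synthesis, was at -4.25 ± 0.16, and the protease gene Jon66Cii at -3.34 ± 0.21. The gene apolpp, the precursor of the main lipoprotein of the haemolymph, was at -3.29 ± 0.11, and the myosin light chain gene Mlc1 at -3.08 ± 0.18. All were called by limma (n = 4 arrays, adjusted p = 3.29e-10 for Vm32E, adjusted p = 1.87e-12 for CycB, adjusted p = 8.26e-21 for Cyp4g1 and apolpp).

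Of 12 eggshell genes 11 were higher in ovary (11 adjusted over the list alone, adjusted p = 6.38e-07), of 43 oogenesis genes 35, with 2 lower (36 and 2 adjusted over the list alone, adjusted p = 1.5e-09), and osk was at 1.63. Eggshell and oogenesis genes had adjusted p = 0.077 and adjusted p = 0.077 with an estimated correlation. DNA replication and cell cycle genes were higher in 21 of 25, with 1 lower (22 and 1 adjusted over the list alone, adjusted p = 2.48e-08). The DNA replication list had adjusted p = 0.0765 with an estimated correlation. Muscle genes were lower in ovary in 15 of 15 cases (15 adjusted over the list alone, median -2.42, adjusted p = 1.13e-17), with the flight muscle genes fln at -3.62, Mlc2 at -3.49 and Act88F at -2.39. Somatic sex-biased genes were lower in 4 of 5 (4 adjusted over the list alone, adjusted p = 2.58e-05). All 26 digestive enzyme genes were lower in ovary (26 adjusted over the list alone, median -2.61, adjusted p = 6.21e-20), deltaTry, a trypsin gene, at -3.36. For digestive enzyme genes this was adjusted p = 0.0771 with an estimated correlation. The yolk genes were lower in ovary than in carcass in 3 of 3 (3 adjusted over the list alone, adjusted p = 0.0374), with Yp1 at -2.44 and Yp2 at -2.32. The yolk list had adjusted p = 0.386 with an estimated correlation. Mitochondrial energy genes were lower in 15 of 17 and higher in 1 (15 and 1 adjusted over the list alone, adjusted p = 0.000432), and immune genes lower in 8 of 11 (8 lower and 1 higher adjusted over the list alone, adjusted p = 0.00236). The mitochondrial energy and immune lists had adjusted p = 0.462 and adjusted p = 0.0507 with an estimated correlation.

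Limma called 3079 of 13111 elements higher in ovary and 3409 higher in female carcass, 300 and 950 at least 2-fold. Ovary-biased genes were more frequent on the X than on the autosomes (29.5 against 24.8%, odds ratio 1.27, Fisher's exact test, adjusted p = 0.000453), and carcass-biased genes less so (23.7 against 28.8%, odds ratio 0.767, Fisher's exact test, adjusted p = 0.000176). Neither passed on elements measured by all arrays (1.07 and 0.856), nor did the former with a 2-fold threshold (1.24). These values leave out the first subarray of arrays 7b and 8b. With it as deposited 3606 elements were called, and Mlc2 (0.18), Yp1 (0.12), Yp2 (0.027) and deltaTry (0.26) turned sign without being called. On those values osk (0.043) and fln (-0.018) were not called either.

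Muscle genes were higher in the male carcass than in testis, and most spermatogenesis genes higher in testis, though that list lost its call with an estimated correlation. Higher in testis were Gpdh3 by 2.95 ± 0.28 (SE, n = 2 arrays), exu, which acts in spermatogenesis as well as in egg patterning, by 2.86 ± 0.26, Mst87F by 2.84 ± 0.23, w-cup by 2.84 ± 0.31 and Mst98Cb by 2.76 ± 0.25. Among the lowest were Cyp4g1 at -3.60 ± 0.23, Mlc1 at -3.27 ± 0.26, the cuticle protein gene Vajk3 at -3.26 ± 0.29, Arr2, a visual arrestin, at -3.25 ± 0.31, and TpnC4, a troponin C of flight muscle, at -3.20 ± 0.29. These genes passed in limma (n = 2 arrays, adjusted p = 1.38e-10 for exu, adjusted p = 5.75e-11 for Mst87F, adjusted p = 1.34e-13 for Cyp4g1, adjusted p = 1.04e-09 for Arr2). Spermatogenesis genes were higher in testis in 30 of 32 cases (30 adjusted over the list alone, median 1.99, adjusted p = 3.91e-16), betaTub85D at 2.55 and dj at 2.65. Accessory gland genes were higher in testis RNA than in carcass in 15 of 17 and lower in 1 (16 and 1 adjusted over the list alone, median 0.98, adjusted p = 0.00376), SP at 1.19 and Mst57Dc at 1.39. Gland tissue in the testis RNA was not tested for. Spermatogenesis and accessory gland genes had adjusted p = 0.0552 and adjusted p = 0.483 with an estimated correlation.

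Muscle genes were lower in testis in 14 of 15 (14 adjusted over the list alone, median -2.66, adjusted p = 1.17e-12). Photoreceptor genes were lower in 10 of 12 (10 adjusted over the list alone, adjusted p = 0.000112) and neuronal genes in 15 of 17, with 2 higher (the same adjusted over the list alone, adjusted p = 0.000432). The photoreceptor and neuronal lists had adjusted p = 0.105 and adjusted p = 0.211 with an estimated correlation. Digestive enzyme genes were lower in 23 of 26 (24 adjusted over the list alone, adjusted p = 4.16e-05). For digestive enzyme genes this was adjusted p = 0.515 with an estimated correlation. Immune genes, lower in 5 of 10 (6 adjusted over the list alone), were at adjusted p = 0.0533, which passed without centring (adjusted p = 0.0498). Limma called 3411 of 13113 elements higher in testis and 3529 higher in the male carcass, 1458 and 885 at least 2-fold. Without array 9 the calls numbered 4458, and with arrays scaled to the same spread 4309, with Mst87F at 1.82 and Cyp4g1 at -2.33. Testis-biased genes made up a smaller share of X-linked than of autosomal genes (25.0 against 30.7%, odds ratio 0.755, Fisher's exact test, adjusted p = 4.08e-05). The odds ratio of X-linked genes toward the carcass (0.872, Fisher's exact test, adjusted p = 0.0544) passed with a 2-fold threshold (0.682), with arrays scaled to the same spread (0.830) and without a dye coefficient (0.861).

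Females exceeded XX flies mutant for transformer 2, whose soma is male, in oogenesis and DNA replication genes, and fell short of them in accessory gland and muscle genes. In females Yp2 was 4.08 ± 0.29 higher (SE, n = 4 arrays), dhd 3.50 ± 0.28, Yp1 3.28 ± 0.27, gnu 2.89 ± 0.19, me31B 2.67 ± 0.16, yl 2.57 ± 0.17 and BicC, an RNA-binding regulator of oogenesis, 2.50 ± 0.22. In the other direction Spn77Bb was at -4.10 ± 0.16, tobi, an insulin-responsive glucosidase gene, at -3.97 ± 0.17, and EbpII at -3.48 ± 0.18. Obp56g was at -3.41 ± 0.10, Acp62F, a seminal protease inhibitor, at -3.36 ± 0.15, and the cuticle protein gene Vajk2 at -3.16 ± 0.23 (n = 4 arrays). All passed in limma (n = 4 arrays, adjusted p = 1.26e-12 for Yp2, adjusted p = 1.61e-19 for Spn77Bb, adjusted p = 3.9e-23 for Obp56g).

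All 18 accessory gland genes were lower in females than in these XX flies (18 adjusted over the list alone, median -2.30, adjusted p = 3.22e-32), SP at -2.60. By contrast 3 of 10 tested spermatogenesis genes were called, 1 higher and 2 lower (1 and 1 adjusted over the list alone, adjusted p = 0.899). The testis tubulin gene betaTub85D was measured on 1 of the 4 arrays and not tested. Oogenesis genes were higher in females in 36 of 44, with 1 lower (the same adjusted over the list alone, adjusted p = 1.38e-14), osk at 2.29 and vas at 1.95. DNA replication and cell cycle genes were higher in 21 of 25 and lower in 1 (the same adjusted over the list alone, adjusted p = 1.97e-12). The 3 yolk genes were higher in females (3 adjusted over the list alone, adjusted p = 7.56e-05), as were 10 of 11 eggshell genes, with 1 lower (the same adjusted over the list alone, adjusted p = 0.00031). Yolk and eggshell genes had adjusted p = 0.0552 and adjusted p = 0.211 with an estimated correlation. Muscle genes were lower in females in 15 of 15 (15 adjusted over the list alone, median -1.87, adjusted p = 1.17e-13), Act88F at -2.13, and mitochondrial energy genes in 16 of 17 (16 adjusted over the list alone, adjusted p = 0.000124). The mitochondrial energy list had adjusted p = 0.423 with an estimated correlation. Odorant binding protein genes were lower in 17 of 24 and higher in 1 (the same adjusted over the list alone, adjusted p = 1.04e-05). For odorant binding protein genes this was adjusted p = 0.0771 with an estimated correlation.

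Limma called 3371 of 12014 elements higher in females and 3416 higher in the XX mutants, 279 and 484 at least 2-fold, and 4462 calls were left with arrays scaled to the same spread and 4410 on the 4 arrays alone. Of 3328 elements higher in females 2390 (71.8%) were higher in ovary than in female carcass, where independent lists would share 836.7, and of 3316 higher in the mutants 2499 (75.4%) were higher in the carcass, where 908.2 would be shared. Part of these overlaps may come from shared RNA. The share higher in females did not differ detectably between X-linked and autosomal genes (odds ratio 1.12, Fisher's exact test, adjusted p = 0.11). X-linked genes were less often higher in the mutants (odds ratio 0.857, Fisher's exact test, adjusted p = 0.0304), which was lost on elements measured by all arrays (0.948).

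**Figure D3:**
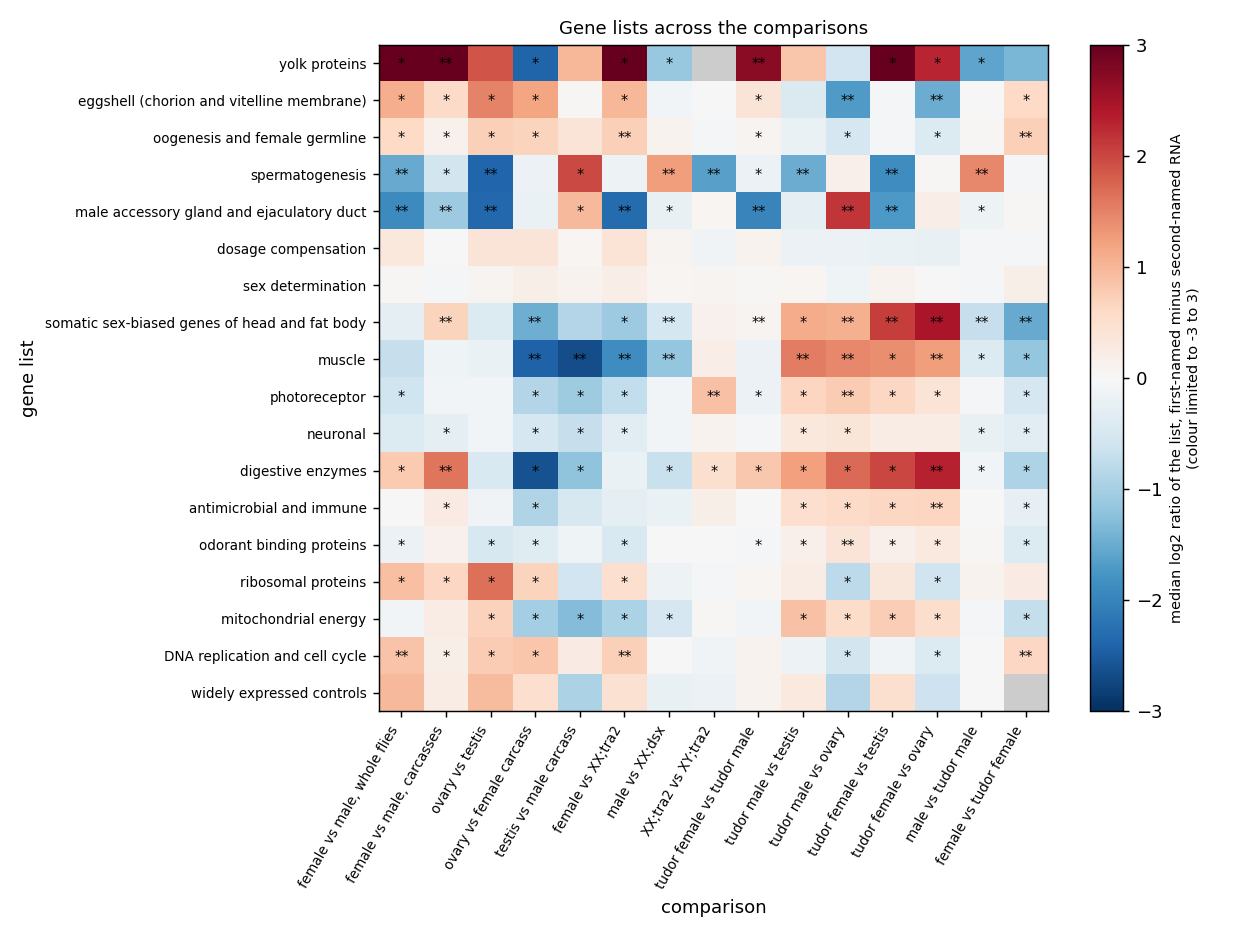
Median log2 ratio (colour, red for higher in the first-named RNA, blue for lower, grey for not tested) of each fixed gene list in each comparison, with an asterisk for lists past the threshold of limma's list test and a double asterisk for those that also pass with an estimated correlation. Accessory gland genes have a median of -1.90 in females over males, -2.30 in females over XX flies mutant for transformer 2 and 0.05 in XX over XY flies mutant for transformer 2.

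Males exceeded XX flies mutant for doublesex in sperm genes, and the mutants exceeded males in muscle genes. In males w-cup was 2.60 ± 0.21 higher (SE, n = 4 arrays), Mst87F 2.29 ± 0.16, dj 2.26 ± 0.29, S-Lap7 2.25 ± 0.17, Mst77F 2.23 ± 0.14 and Pen, an importin gene, 2.15 ± 0.20. In the other direction tobi was at -3.37 ± 0.17, Vajk2 at -2.38 ± 0.23, the cuticle protein gene Cpr92F at -2.35 ± 0.18, and Act88F at -1.89 ± 0.18. Each passed in limma (n = 4 arrays, adjusted p = 7.06e-10 for w-cup, adjusted p = 9.3e-14 for Mst77F, adjusted p = 2.06e-12 for tobi, adjusted p = 2.06e-10 for Act88F). Spermatogenesis genes were higher in males in 27 of 31 (28 adjusted over the list alone, median 1.26, adjusted p = 1.6e-27). Accessory gland genes were lower in males than in the mutants in 5 of 18 (5 adjusted over the list alone, median -0.22, adjusted p = 0.0163), and SP was at 0.10, not called. The list had adjusted p = 0.578 with an estimated correlation. All 3 yolk genes were lower in males (3 adjusted over the list alone, adjusted p = 0.0406), Yp2 at -1.65, Yp1 at -1.14 and Yp3 at -0.71. The yolk list had adjusted p = 0.392 with an estimated correlation. The call of Yp3 was lost without any of the arrays 13a (-0.67), 13b (-0.76), 14a (-0.61) or 14b (-0.80).

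Muscle genes were lower in males in 12 of 15 (12 adjusted over the list alone, median -1.17, adjusted p = 5.94e-14) and somatic sex-biased genes in 4 of 7, with 1 higher (5 and 1 adjusted over the list alone, adjusted p = 6.16e-05). Digestive enzyme genes were lower in 16 of 26 (17 adjusted over the list alone, adjusted p = 4.12e-05), and mitochondrial energy genes in 11 of 17 (12 adjusted over the list alone, adjusted p = 3.7e-05). For digestive enzyme and mitochondrial energy genes these were adjusted p = 0.515 and adjusted p = 0.383 with an estimated correlation. Limma called 1913 of 12633 elements higher in males and 1468 higher in the mutants, 510 and 94 at least 2-fold, and 2201 in all without array 14a. Of 1908 elements higher in males 1708 (89.5%) were higher in testis than in male carcass, where independent lists would share 494.2 and part may come from shared RNA. X-linked genes were called higher in males less often than autosomal genes (13.5 against 18.4%, odds ratio 0.695, Fisher's exact test, adjusted p = 2.91e-05), which was lost on elements measured by all arrays (0.665). The odds ratio toward the mutants was 1.04 (Fisher's exact test, adjusted p = 0.679) and 0.654, turned, with a 2-fold threshold.

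Among flies mutant for transformer 2, XY flies exceeded their XX siblings in sperm genes, and XX flies exceeded XY flies in genes of the eye. Arr1 was 2.04 ± 0.15 higher in XX flies (SE, n = 4 arrays), Arr2 1.89 ± 0.21, the light-gated channel gene trp 1.12 ± 0.14, chp, a photoreceptor adhesion protein gene, 1.05 ± 0.09, and Ggamma30A, a visual G protein subunit gene, 1.02 ± 0.12. In XX over XY flies Mst77F was at -3.15 ± 0.14, Pen at -2.77 ± 0.20, S-Lap7 at -2.71 ± 0.17, Mst98Cb at -2.64 ± 0.17 and betaTub85D at -2.27 ± 0.13. Each gene was called by limma (n = 4 arrays, adjusted p = 1.2e-12 for Arr1, adjusted p = 1.96e-07 for trp, adjusted p = 2.12e-17 for Mst77F). All 10 tested photoreceptor genes were higher in XX flies (10 adjusted over the list alone, median 0.87, adjusted p = 7.42e-14), and 26 of 28 spermatogenesis genes were lower (28 adjusted over the list alone, median -1.63, adjusted p = 3.73e-36), both also with an estimated correlation. None of 18 accessory gland genes was called by limma (0 adjusted over the list alone, 0 at an unadjusted p below 0.05, median 0.05, adjusted p = 0.41 for the list). Digestive enzyme genes were higher in XX flies in 8 of 26 (11 adjusted over the list alone, adjusted p = 8.37e-05). Their list had adjusted p = 0.541 with an estimated correlation.

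Limma called 572 of 11025 elements higher in XX and 1688 higher in XY flies, 17 and 655 at least 2-fold, and 790 in all on the 4 arrays alone. Array 15b ran apart, with a correlation across elements of 0.570 with 15a, 0.0637 with 16a and 0.176 with 16b, and without it 2164 elements were called. On that array digestive enzyme genes had a median of -0.86 and photoreceptor genes of -0.35 relative to the other arrays. X-linked genes were more often higher in XX flies than autosomal genes (7.95 against 5.06%, odds ratio 1.62, Fisher's exact test, adjusted p = 0.000221) and less often higher in XY flies (13.9 against 18.9%, odds ratio 0.689, Fisher's exact test, adjusted p = 4.08e-05). The first was lost with repeats averaged (1.35), with a 2-fold threshold (1.26) and on elements measured by all arrays (1.596), the second on the latter (0.718). Of 1683 elements higher in XY flies 1620 (96.3%) were higher in testis than in male carcass, where independent lists would share 443.9.

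Flies without a germline still differed by sex in yolk and accessory gland genes. In tudor females Yp2 was 2.97 ± 0.42 higher than in tudor males (SE, n = 2 arrays), Yp1 2.49 ± 0.40, fit 1.95 ± 0.26, Obp99a 1.80 ± 0.16 and eloF, an elongase gene of female pheromone synthesis, 1.43 ± 0.14. EbpII was at -3.12 ± 0.26, Obp56g at -2.94 ± 0.15, Acp62F at -2.81 ± 0.22, Mst57Dc at -2.72 ± 0.19 and SP at -2.29 ± 0.20. All were called by limma (n = 2 arrays, adjusted p = 2.43e-05 for Yp2, adjusted p = 1.49e-09 for Obp99a, adjusted p = 5.94e-16 for Obp56g, adjusted p = 1.1e-09 for SP). Accessory gland genes were lower in females in 16 of 18 (18 adjusted over the list alone, median -1.99, adjusted p = 4.86e-177), and the 3 yolk genes were higher (3 adjusted over the list alone, adjusted p = 7.82e-18). In the somatic list 3 of 7 genes were higher and 1 was lower (3 and 2 adjusted over the list alone, adjusted p = 2.09e-05). Digestive enzyme genes were higher in females in 2 of 26 over all genes (17 adjusted over the list alone, median 0.80, adjusted p = 1.58e-15). The digestive enzyme list had adjusted p = 0.134 with an estimated correlation. No eggshell, oogenesis or spermatogenesis gene was called by limma over all elements (0 of 11, 33 and 21 tested). At an unadjusted p below 0.05, 4 eggshell and 3 oogenesis genes were higher in females and 5 spermatogenesis genes lower. Adjusted over the list alone, 2 eggshell genes were higher, 0 oogenesis genes differed and 3 spermatogenesis genes were lower, and betaTub85D was at -0.56, not called. Its value was -0.15 without array 17a and -0.98 without 17b, and it was called with arrays scaled to the same spread (-1.71, adjusted p = 0.00133). These lists still shifted as a whole, eggshell at a median of 0.38 (adjusted p = 0.00055), oogenesis at 0.07 (adjusted p = 0.0328) and spermatogenesis at -0.18 (adjusted p = 0.000454). For eggshell, oogenesis and spermatogenesis genes these were adjusted p = 0.23, adjusted p = 0.572 and adjusted p = 0.423 with an estimated correlation.

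Limma called 39 of 11495 elements higher in tudor females and 104 higher in tudor males, 16 and 68 at least 2-fold. Without array 17a 55 were called, and Yp3 (2.70 with both arrays, 2.30 without 17a), Fad2 (1.63 and 0.84), Send1 (1.79 and 1.49) and Cyp4d21 (-1.28 and -0.90) lost their calls. Among elements tested in both comparisons, of 39 higher in tudor females 37 were also higher in female carcasses, where independent lists would share 4.1, and of 90 higher in tudor males 77 were also higher in male carcasses, where 7.86 would be. With arrays scaled to the same spread 46.2% of 2105 calls, rather than 27.3% of 143, were higher in females, all 143 among them, and Yp2 was at 7.82. On their own arrays 290 elements were called, and with a coefficient per RNA source 340. On the X, 3 of 1351 genes were called higher in tudor males against 75 of 6534 autosomal genes (odds ratio 0.192, Fisher's exact test, adjusted p = 0.00132). This was lost on elements measured by all arrays, where the odds ratio was 0. Toward tudor females the odds ratio was 1.26 (Fisher's exact test, adjusted p = 0.679), past the threshold with arrays scaled to the same spread (1.49).

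The sex effect in carcasses and in tudor flies was also compared directly, and limma called 27 of 10557 elements, 18 more female-biased in carcasses and 9 in tudor flies. The number rested on single arrays. Without array 17b it was 0 (349 elements at an unadjusted p below 0.05), without 17a 2, and without 4a 7. It was 3 with repeats averaged, 0 without a dye coefficient (558 unadjusted) and 0 on the 6 arrays alone (703 unadjusted), and 949 with arrays scaled to the same spread.

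**Figure D4:**
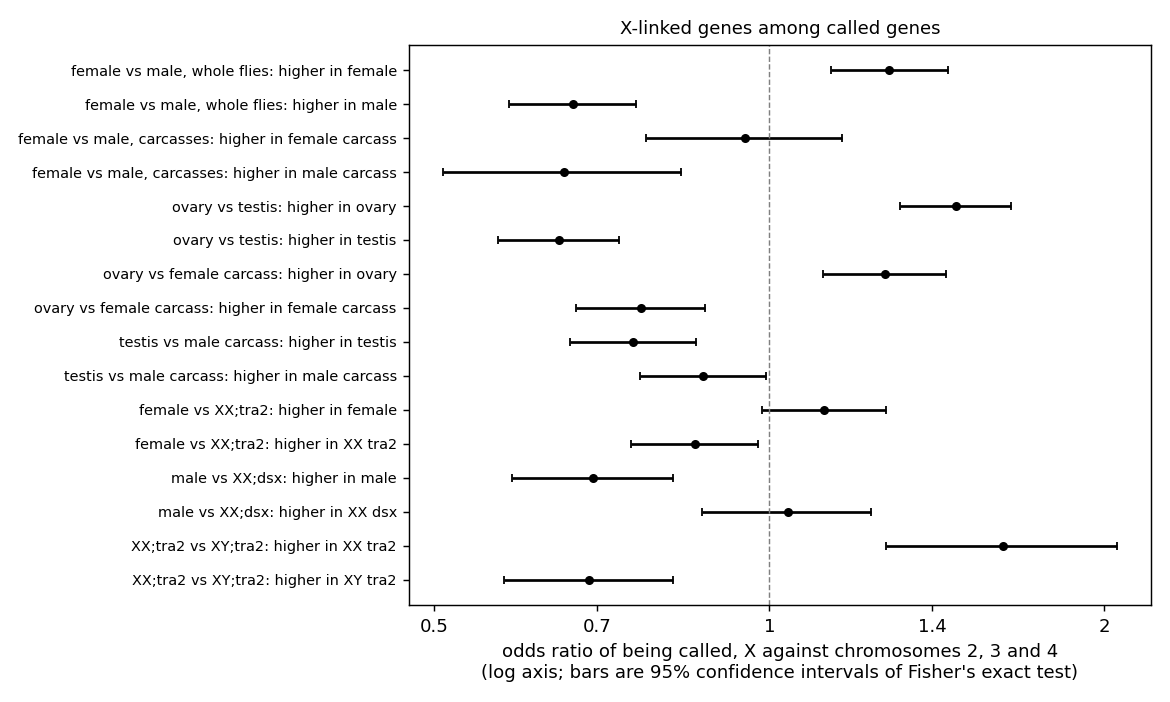
Odds ratio of being called for X-linked against autosomal genes (log axis) in both directions of 8 comparisons, with bars for its 95% confidence interval. The odds ratio was 1.47 for genes higher in ovary than in testis and 0.647 for genes higher in testis.

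Males exceeded tudor males in sperm genes, while tobi was higher in tudor males. The same gene was higher in each mutant stock than in the yellow white flies, at -3.97 in females over XX flies mutant for transformer 2, -3.37 in males over XX flies mutant for doublesex and -3.29 in females over tudor females. Between tudor females and males it was at 0.07, not called. In males w-cup was 2.46 ± 0.31 higher (SE, n = 2 arrays), Mst87F 2.33 ± 0.23 and dj 2.31 ± 0.43. The glucosidase gene tobi was at -2.96 ± 0.26 (limma, adjusted p = 4.65e-06 for w-cup, adjusted p = 2.54e-08 for Mst87F, adjusted p = 4.7e-08 for tobi). Of the 3 yolk genes 2 were lower in males (3 adjusted over the list alone, adjusted p = 0.00219). The yolk list had adjusted p = 0.149 with an estimated correlation. Both calls were lost without array 22 or 23, Yp2 (-1.73 ± 0.43) at -1.93 and -1.52 and Yp1 (-1.58 ± 0.40) at -1.455 and -1.71. Spermatogenesis genes were higher in males in 18 of 26 (21 adjusted over the list alone, median 1.44, adjusted p = 1.18e-36), betaTub85D at 2.01. Accessory gland genes were lower in males in 2 of 18 (2 adjusted over the list alone, median -0.15, adjusted p = 0.0231), and SP was at 0.20, not called. The list had adjusted p = 0.597 with an estimated correlation. In the somatic list 4 of 7 were lower in males and 1 higher (5 and 1 adjusted over the list alone, adjusted p = 4.8e-05). Limma called 800 of 13355 elements higher in males and 182 higher in tudor males, 411 and 30 at least 2-fold, with 437 in all without array 23, 602 without array 22 and 1475 with repeats of the other comparisons averaged. With arrays scaled to the same spread 60.6% of 2631 calls, rather than 81.5% of 982, were higher in males, 981 of the 982 among them. Of 799 elements higher in males 768 (96.1%) were higher in testis than in male carcass, where independent lists would share 193.8. The X-linked share called higher in males was lower than the autosomal one (3.59 against 7.89%, odds ratio 0.435, Fisher's exact test, adjusted p = 2.8e-09).

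Females exceeded tudor females in oogenesis and DNA replication genes and fell short of them in somatic sex-biased genes. In females dhd was 2.50 ± 0.41 higher (SE, n = 2 arrays) and me31B 1.88 ± 0.24, while tobi was at -3.29 ± 0.26, fit at -2.39 ± 0.27 and Send1 at -2.31 ± 0.32 (limma, adjusted p = 3.54e-05 for dhd, adjusted p = 2.06e-08 for tobi). Oogenesis genes were higher in females in 27 of 40 (30 adjusted over the list alone, adjusted p = 4.88e-12) and DNA replication and cell cycle genes in 16 of 22 (17 adjusted over the list alone, adjusted p = 2.63e-09). Eggshell genes were higher in 6 of 11 and lower in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0361), a list call lost with arrays scaled to the same spread (adjusted p = 0.0716). The eggshell list had adjusted p = 0.515 with an estimated correlation. Somatic sex-biased genes were lower in females in 5 of 6 (5 adjusted over the list alone, median -1.52, adjusted p = 1.53e-10). Muscle genes were lower in 14 of 15 (14 adjusted over the list alone, adjusted p = 1.63e-09) and digestive enzyme genes in 19 of 26 (22 adjusted over the list alone, adjusted p = 5e-08). For muscle and digestive enzyme genes these were adjusted p = 0.0673 and adjusted p = 0.381 with an estimated correlation. Limma called 1630 of 10484 elements higher in females and 1562 higher in tudor females, 140 and 295 at least 2-fold, with 647 in all without array 25 and 2066 without array 24. Of 1624 elements higher in females 1455 (89.6%) were higher in ovary than in female carcass, where independent lists would share 418.4. X-linked genes were less often higher in tudor females (odds ratio 0.79, Fisher's exact test, adjusted p = 0.0135).

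The remaining 4 comparisons set germline-less flies against gonads. Cyp4g1 was 3.36 ± 0.23 higher in tudor males than in testis, 4.55 ± 0.23 higher in tudor males than in ovary, and 4.01 ± 0.23 higher in tudor females than in ovary (SE, n = 2 arrays each). Yp2 was 3.87 ± 0.42 higher in tudor females than in testis (n = 2 arrays). Against testis, Mst87F was at -3.05 ± 0.23 in tudor males and -3.13 ± 0.23 in tudor females, and tHMG2, a testis gene for a DNA-binding protein, at -3.01 ± 0.19 and -3.25 ± 0.19. Against ovary, dhd was at -3.71 ± 0.40 in tudor males and -2.64 ± 0.40 in tudor females, and Vm32E at -3.10 ± 0.30 and -2.40 ± 0.30. All were called (limma, adjusted p = 1.11e-12 for Cyp4g1 against testis, adjusted p = 2.97e-11 for Mst87F in tudor males, adjusted p = 2.35e-08 for dhd in tudor males, adjusted p = 8.51e-06 for dhd in tudor females). Accessory gland genes were called between tudor males and testis in 4 of 18, 1 higher and 3 lower in tudor males (the same adjusted over the list alone, adjusted p = 0.555). They were higher in tudor males than in ovary in 17 of 17 (17 adjusted over the list alone, median 2.16, adjusted p = 2.47e-31) and lower in tudor females than in testis in 18 of 18 (18 adjusted over the list alone, median -1.72, adjusted p = 2.18e-15). Eggshell genes were lower than in ovary in 11 of 11 in tudor males (11 adjusted over the list alone, adjusted p = 5.37e-15) and in tudor females (11 adjusted over the list alone, adjusted p = 1.32e-11). Spermatogenesis genes were lower than in testis in 26 of 33 in tudor males (29 adjusted over the list alone, adjusted p = 4.86e-21) and 25 of 28 in tudor females (26 adjusted over the list alone, adjusted p = 4.42e-20). Digestive enzyme genes were higher in tudor females than in ovary in 25 of 26 (26 adjusted over the list alone, adjusted p = 1.81e-34).

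Limma called 2079 elements higher and 2225 lower in tudor males than in testis, 1973 and 1745 against ovary, and for tudor females 2060 and 2243 against testis and 1525 and 1433 against ovary, of 13415, 12197, 11558 and 11965 tested. These arrays had 1 dye orientation and their counts leaned on single arrays. Tudor males against testis fell to 1517 calls without 18a, tudor males against ovary to 1609 without 19a and 2336 without 19b, tudor females against testis to 2284 without 20a, and tudor females against ovary to 1088 without 21b and 1817 without 21a. The direct gonad difference correlated across elements with that by way of tudor males at 0.940, tudor females 0.934 and carcasses 0.963. It was 1.48, 1.54 and 0.944 times the path. Ratios by way of tudor flies thus ran smaller. Whether this shrank tudor sex effects stays open.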

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

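The test of genes at least 2-fold higher in ovary and the grouping by hybridisation were chosen after the results were seen. The other tests here were chosen beforehand.

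The sex effect differed between whole flies and carcasses for 4297 elements and between carcasses and tudor flies for 27 (limma, tests of the difference itself). For the first, regrouping the 8 arrays in all 35 ways gave at most 3414 elements in any other grouping, with 1 of the 35, the real one, reaching 4297. This excludes chance only if repeats of a hybridisation count as separate arrays. Kept together, the 4 hybridisations allow 3 groupings, too few for a share under 0.05, of which 1, the real one, gave 4297 and the others at most 1. The counts of the 4-array comparisons were set against the 8 ways of assigning signs to their arrays, which are too few for a share under 0.05. In each of them 1 assignment, the real one, gave the real count. The real count and the highest of the other assignments were 7365 and 3436 for whole females and males, 2185 and 516 for the carcasses, 8758 and 6356 for the gonads, and 6488 and 4528 for ovary against carcass. They were 6787 and 3353 for females against XX flies mutant for transformer 2, 3381 and 37 for males against XX flies mutant for doublesex, and 2260 and 1867 for XX against XY flies mutant for transformer 2.

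Single arrays stood far from the other arrays of their comparison for 6 of 188 gene and comparison pairs, where chance would give 9.4. In whole females over males dhd was at 3.88 on array 1a and between 3.17 and 3.22 on the others. In the carcasses Yp1 was at 5.59 on array 4a and between 3.64 and 3.93 elsewhere. In ovary over female carcass Mlc1 was at -2.53 on array 7a and between -3.32 and -3.21 on the others. In females over XX flies mutant for transformer 2 yl was at 3.73 on array 12a and between 2.17 and 2.21 elsewhere. In ovary over testis twe was at -0.49 on array 6a and between 0.14 and 0.23 on the others. In males over XX flies mutant for doublesex betaTub85D was at 1.495 on array 14b and between 2.04 and 2.12 elsewhere.

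The carcass and tudor difference was weighed against gonad RNA left in carcasses and against dye, over gene sets, not over the 27 elements. Over 188 genes at least 4-fold higher in testis than in male carcass, and not higher in ovary than in female carcass, the sex effect was lower in carcasses by a median difference of -0.48 (95% confidence interval -0.52 to -0.43), with medians of -0.62 in carcasses and -0.11 in tudor flies, and over all genes the difference was -0.0033. This is what testis RNA left in male carcasses would give, and may account for part of the difference. Over 99 genes at least 2-fold higher in ovary the difference was 0.24 (0.20 to 0.30), in the direction that ovary RNA left in female carcasses would give. At 4-fold only 1 gene remained (0.70), so that test decided nothing, and neither did a correlation of -0.278 across elements between the difference and the dye effect, since tudor flies were hybridised in 1 orientation, and the difference of the flies in genotype and germline stays open, untested.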

How the results depend on the processing

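The settings for the first subarray of arrays 7b and 8b, and the carcass and tudor difference on its own arrays, were chosen after seeing the data. Of 297 gene and comparison pairs named, 2233 other settings left 2186 on the same side of the threshold and in the same direction, 38 lost the call, 3 gained it and 6 turned sign. Among 990 settings without an array, 952 stayed, 34 lost the call and 4 turned. Where that left 1 array of a comparison, it was assumed to vary like the others. No list called at the preset correlation changed direction with arrays scaled to the same spread or without centring, and the largest move of the median of all genes by any setting was -0.0367 (ovary against testis, without centring). No paired analysis was possible because the hybridisation numbers are not shared between comparisons. The unknown background correction and filter of the deposited values limit what weak spots show. Unless a cause is named, the cause was not tested.

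A 2-fold threshold admits fewer elements by construction, and calls numbered 1333 for whole flies, 231 for carcasses, 2529 for gonads, 1250 for ovary against carcass, 2343 for testis against carcass, 763 for females against XX;tra2, 604 for males against XX;dsx, 672 for XX;tra2 against XY;tra2, 84 for tudor flies by sex, 1252 and 746 for tudor males against testis and ovary, 1348 and 597 for tudor females against testis and ovary, 441 for males and 435 for females against tudor flies, and 688 for the whole-fly and carcass difference. X odds ratios lost their call for whole females (1.01), ovary over carcass (1.24) and XX;tra2 (1.26), gained it for male carcass over testis (0.682) and turned for XX;dsx over male (0.654).

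Elements measured on all arrays are fewer by construction. They gave 2220, 900, 2661, 2317, 2034, 2363, 957, 517 and 20 calls for the comparisons in the order just used up to tudor flies by sex, 1270 and 1433 for tudor males against testis and ovary, 1401 and 1236 for tudor females, 163 for males and 1147 for females against tudor flies, 1495 for the whole-fly and carcass difference and 9 for the carcass and tudor difference. X odds ratios lost their call for whole females (1.26) and males (0.782), male carcass over female (0.753), testis over ovary (0.791), ovary over carcass (1.07), carcass over ovary (0.856), XX;tra2 over female (0.948), male over XX;dsx (0.665), XX;tra2 over XY;tra2 (1.596), XY;tra2 (0.718) and tudor male (0), and gained it for female carcass over male (0.637).

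Arrays scaled to the same spread gave 4383 calls for whole flies, 5090 for gonads, 4309 for testis against carcass, 4462 for females against XX;tra2, 2105 for tudor flies by sex, 2631 for males against tudor males, 1000 for the whole-fly and carcass difference and 949 for the carcass and tudor difference, and X odds ratios past the threshold for male carcass over testis (0.830) and tudor female (1.49). Scaling stretches arrays of small spread and shrinks the others by construction. A coefficient per RNA source, which adds indirect paths, gave 6573 and 6695 for tudor males against testis and ovary, 6643 and 6046 for tudor females, and 340 for tudor flies by sex, and turned twe in the gonads to -0.052. On their own arrays whole flies gave 3971, carcasses 174, females against XX;tra2 4410, XX;tra2 against XY;tra2 790, tudor flies by sex 290, tudor males against testis 2761 and against ovary 1731, tudor females against ovary 1708, and the carcass and tudor difference 0 (limma, 703 at an unadjusted p below 0.05).

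Without a dye coefficient carcasses gave 1086, tudor females against ovary 1962 and the carcass and tudor difference 0 (limma, 558 unadjusted), and X odds ratios turned for female carcass (1.02) and XX;dsx over male (0.980) and passed for male carcass over testis (0.861). With repeats averaged the carcass and tudor difference gave 3, males against tudor males 1475 and tudor females against ovary 1929, and X odds ratios turned for female carcass (1.03) and XX;dsx (0.894) and lost the call for XX;tra2 over XY;tra2 (1.35). Arrays taken as independent gave 15 for the carcass and tudor difference. Without centring it was 17, and twe in the gonads was at -0.015. With the correlation estimated 45 of 142 list calls were left. With 7b and 8b as deposited, ovary against carcass gave 3606, Mlc2 was at 0.18, Yp1 at 0.12, Yp2 at 0.027 and deltaTry at 0.26, all uncalled and turned, and the gonad difference by way of the carcasses correlated with the direct one at 0.816 rather than 0.963. Turned, they gave 6843, and without both arrays 5722.

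Leaving out 1 array at a time gave from 797 to 2297 calls for carcasses, 4458 to 5243 for testis against carcass, 2201 to 2903 for males against XX;dsx, 55 to 97 for tudor flies by sex, 1517 to 3391 and 1609 to 2336 for tudor males against testis and ovary, 2284 to 3152 and 1088 to 1817 for tudor females, 437 to 602 for males and 647 to 2066 for females against tudor flies, and 0 (limma, 349 unadjusted) to 36 for the carcass and tudor difference. It took twe in the gonads from -0.057 to 0.18 and SP in males against tudor males from -0.050 to 0.46, neither called with all arrays. In the other comparisons no array moved a count by more than 1.5 times.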

Other observations

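All tests on arrays 7b, 8b and 15b were chosen after the results were seen.

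Ribosomal protein genes differed among themselves in the gonads. Of 38 tested, 32 were higher in ovary than in testis and 5 lower (the same counts adjusted over the list alone, median 1.66, adjusted p = 7.01e-06 by limma's list test, and adjusted p = 0.462 with an estimated correlation). RpLP2, a stalk protein gene of the large subunit, was at 2.09, whereas the paralogues RpL10Aa, RpL22-like and RpS19b were at -3.35, -1.16 and -0.93, each called higher in testis (n = 4 arrays). Against the male carcass RpL10Aa was 2.57 higher in testis and RpL22-like 1.09, while the list was not shifted (37 genes, 4 higher and 12 lower in testis, 4 and 11 adjusted over the list alone, adjusted p = 0.176).

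Mitochondrial energy genes ran low in testis. They were lower there than in the male carcass in 16 of 17 cases (17 adjusted over the list alone, median -1.30, adjusted p = 1.92e-06, and adjusted p = 0.277 with an estimated correlation), with the ATP synthase subunit genes ATPsynbeta at -2.52 and blw at -2.50 (n = 2 arrays). Ovary exceeded testis in 10 of 17 (10 adjusted over the list alone, adjusted p = 0.0357, and adjusted p = 0.679 with an estimated correlation), ATPsynbeta at 1.605 and blw at 1.58. Oogenesis genes were not shifted as a list between testis and male carcass (18 higher in testis and 5 lower of 41, 20 and 5 adjusted over the list alone, adjusted p = 0.126), nor were DNA replication and cell cycle genes (9 and 1 of 21, the same adjusted over the list alone, adjusted p = 0.227). Of single genes, exu was at -1.73 in ovary over testis, and BicC, at 2.02, and Orc3, a subunit of the replication origin complex, at 1.99, were higher in testis than in male carcass. In males over XX flies mutant for doublesex exu was at 2.03 and BicC at 1.03.

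On the first subarray of arrays 7b and 8b, ratios of ovary to female carcass ran opposite to the path through testis and male carcass (r across elements -0.922 and -0.910), while the second subarray of the same arrays followed it (0.903 and 0.912). Arrays 7a and 8a followed the path on the first subarray (0.902 for both), which argues against those 2 being the ones turned (lower r 0.902). In the sum of 7b and 8b the RNA ratio cancels and the dye effect stays, and on the first subarray that sum correlated with the mean of the mixed RNA arrays at 0.578 (95% confidence interval 0.558 to 0.598, 4125 elements), although those 2 arrays correlated with each other at only 0.0455 there and the sum followed 27b (0.719) and not 27a (0.012). It also followed the dye effect of the other 6 comparisons of 4 arrays, at 0.735 (0.716 to 0.753, 2400 elements), which a change of sign in the deposited values would have turned and which therefore argues against that. These values are consistent with an exchange of probes or of slides between the 2 hybridisations, and no biological explanation was tested.

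Array 15b, of XX against XY flies mutant for transformer 2, ran apart from 15a, 16a and 16b, as given above. Its difference from arrays 16a and 16b correlated with the mixed RNA arrays at 0.413, so a dye effect may contribute, but 15a had 0.548 and is not set apart. The duplicate spots of 15b correlated at 0.846, below the median of the arrays though not the lowest, and its highest correlation in size with another comparison was -0.529, with males over tudor males. Neither poor spots nor other RNAs can be told from these values. Ribosomal protein genes were at -0.91, digestive enzyme genes at -0.86 and mitochondrial energy genes at -0.63 on 15b relative to the other arrays (medians), and no biological explanation was tested.

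The direct tudor sex difference correlated across elements with its path by way of testis at 0.792, ovary 0.773 and whole flies 0.406. It was 0.880, 0.875 and 0.212 times the path. Only the last path uses arrays without tudor RNA.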
